A study of Rattus norvegicus with 10 samples.

How the data were processed

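Total RNA from 10 rat lacrimal glands was hybridised to Affymetrix rat arrays, one array per gland. Per the labels, 5 glands were taken 7 days after section of the greater superficial petrosal nerve, 3 were contralateral control glands at the same time, 1 came from an unoperated animal and 1 was taken 7 days after a sham operation. The labels number the contralateral and denervated glands but do not say that they came from separate animals, so p-values measure only the spread between these samples, which may be technical. The titles call 3 control glands contralateral, while their descriptions place them on the same side as the experimental gland. The titles were followed here.

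The deposited values are linear probe set intensities, 1 positive value per probe set and array for 8799 probe sets. The authors had scaled each array to a common level, as the deposited values themselves show: with 2% trimmed at each end, the array means ran from 2505 to 2507, a range of 0.0718% of their mean. The software, its version and detection calls are not given in the sources used here. Because the trimmed means lay within 5% of each other, the deposited scaling was kept. Intensities below the 20th percentile of all values, 156.2, were set to that floor and log2 was taken. Values at the floor have no order, and differences that involve them understate the change. The 59 array control probe sets were left out, and of the remaining 8740 those with a mean log2 intensity above the 30th percentile were tested, 6118 in all. The number of arrays limits the precision: the median standard error of a log2 difference between denervated and control glands was 0.50.

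Gene symbols came from the array's platform annotation, with gene IDs matched to a RefSeq gene table of the GRCr8 assembly, used for names only. Of the 8740 probe sets, 7006 carried 1 symbol, 308 carried several and 1426 were not listed. The gene IDs of 6985 single-symbol probe sets were found in the table. Probe sets with several symbols or none were tested but not named. The tested probe sets with 1 symbol covered 3621 genes. No genome coordinates are given.

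Differences were tested on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment over the probe sets and a threshold of 0.05. Denervated glands were compared with all 5 control glands in a fit of 2 classes. A fit of 3 classes gave denervated against contralateral glands, and each of these against the unoperated and sham glands as 1 class. The sham and unoperated glands were set against each other as values only, since each is 1 gland. Gene lists, 29 in all, were compared with the other genes by limma's camera with a preset correlation between genes of 0.01, using for each gene the probe set with the highest mean and testing lists with at least 5 measured genes. A list's median and mean are over its measured genes. RNA quality was checked by the log2 ratio of the 3' to the 5' control probe set of 3 genes with an exact permutation test.

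The samples' groups, tests, lists and most alternatives were fixed before the data were examined, as was the rule for the genes named. That rule takes, for denervated against all control and against contralateral glands, the 10 genes with the largest difference in each direction among those past the threshold, filled up by the smallest unadjusted p where fewer pass. It takes the 5 smallest p in each direction for the contrasts with the unoperated and sham glands, 4 members of each list that passed, up to 2 of any other list named, and a fixed set of receptor and secretion genes, 1 of which is not reported here. Where a named gene has other probe sets, their differences are given if the sign differs.

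Alternatives were quantile and median scaling, other floors and filters, no variance trend, array weights, 1 probe set per gene, the glands' numbers as a block, camera with an estimated correlation, the fry rotation test, and leaving out each gland. Fits with sets of arrays as a block, or without 3 arrays that stand apart, were added after the data were seen. In 10 simulations of denervated against control glands with 200 of 6118 probe sets changed, the same steps recovered 14.0% of 2-fold and 71.7% of 4-fold changes, and 5.41% of calls were false. The simulated noise was independent between probe sets and arrays, and only probe sets averaging more than 4-fold above the floor were changed. The real arrays share differences across many probe sets, so these rates need not hold for them. Figures were drawn with matplotlib 3.10.9.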

Results

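Messenger RNA levels were measured in 10 rat lacrimal glands, the glands that secrete the watery part of the tear film. The greater superficial petrosal nerve carries their parasympathetic supply. Denervated glands (n = 5) were taken 7 days after this nerve was sectioned. The 5 control glands were 3 contralateral glands, 1 unoperated gland and 1 sham-operated gland. Median intensity ran from 554 to 979 over the 10 arrays, and correlations of log2 intensity between arrays, across probe sets, from 0.715 to 0.912.

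The first comparison asked how denervated glands differed from control glands. Dmbt1, a secreted scavenger receptor of mucosal defence, had a mean log2 intensity of 14.81 ± 0.92 (SD, n = 5) in denervated and 12.52 ± 0.65 (SD, n = 5) in control glands, a 4.86-fold higher level. Rrbp1, a ribosome-binding protein of the rough endoplasmic reticulum, was lower, with 12.27 ± 0.50 (SD, n = 5) against 13.85 ± 0.55 (SD, n = 5). All 5 denervated glands lay above all controls for Dmbt1 and below all controls for Rrbp1. Neither gene passed the test, each with an adjusted p of 0.384 from limma.

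No probe set passed: limma gave 0 of 6118 at an adjusted p under 0.05, and 592 at an unadjusted p under 0.05, where 306 are expected by chance. Of these, 307 were higher and 285 lower in denervated glands. Arrays share differences across many probe sets, and 13 of 100 splits of the arrays, the real one included, gave at least 592. Chance is thus not excluded for this count. The intensities of denervated and control glands did not overlap for 102 probe sets, 1.67% of those tested, against 0.794% by chance, a share not compared with other splits. Leaving out the gland denervated 1 gave 70 passing probe sets, 48 higher and 22 lower, and 0 when a block for contralateral 1, sham and denervated 1, chosen after the data were seen, was fitted as well.

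None of the genes named next passed. Among the higher ones, log2 differences (± SE) were 2.18 ± 0.48 for Aif1, a calcium-binding protein of macrophages, and 2.37 ± 0.53 for Casp1, the protease that activates interleukin-1 beta, whose other probe sets differed by 0.50 and 0.26. They were 1.60 ± 0.38 for Slfn5, 2.14 ± 0.52 for the chemokine scavenger receptor Ackr3, 1.05 ± 0.26 for the immunoproteasome subunit Psmb8 and 2.10 ± 0.53 for the transcription factor Fos, with 0.48 and 0.30 at its other probe sets. Aif1 was at the floor in 3 control glands. The small GTPase Rab12 differed by 2.20 ± 0.57, Trrap by 2.08 ± 0.51 and LOC102549726 by 2.43 ± 0.59, with 1.14 at another probe set. Among the lower ones were Calr, a calcium-binding chaperone of the endoplasmic reticulum (-1.62 ± 0.43), Slc35b1, a transporter of the same membrane (-1.08 ± 0.24), and Ica1, a protein of secretory vesicles (-1.12 ± 0.25). The amino acid transporter Slc7a5 differed by -2.07 ± 0.53, the phospholipase Pla2g6 by -1.36 ± 0.31, Or2z2 by -2.17 ± 0.56 and Oaz3 by -1.99 ± 0.52. Tissue kallikrein, Klk1, and the protein kinase Rock1 differed by -2.12 ± 0.48 and -2.11 ± 0.48, and each was at the floor in 4 denervated glands, while Klk1 differed by -0.91 at another probe set. All of these had an adjusted p of 0.434 from limma.

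**Figure D1:**
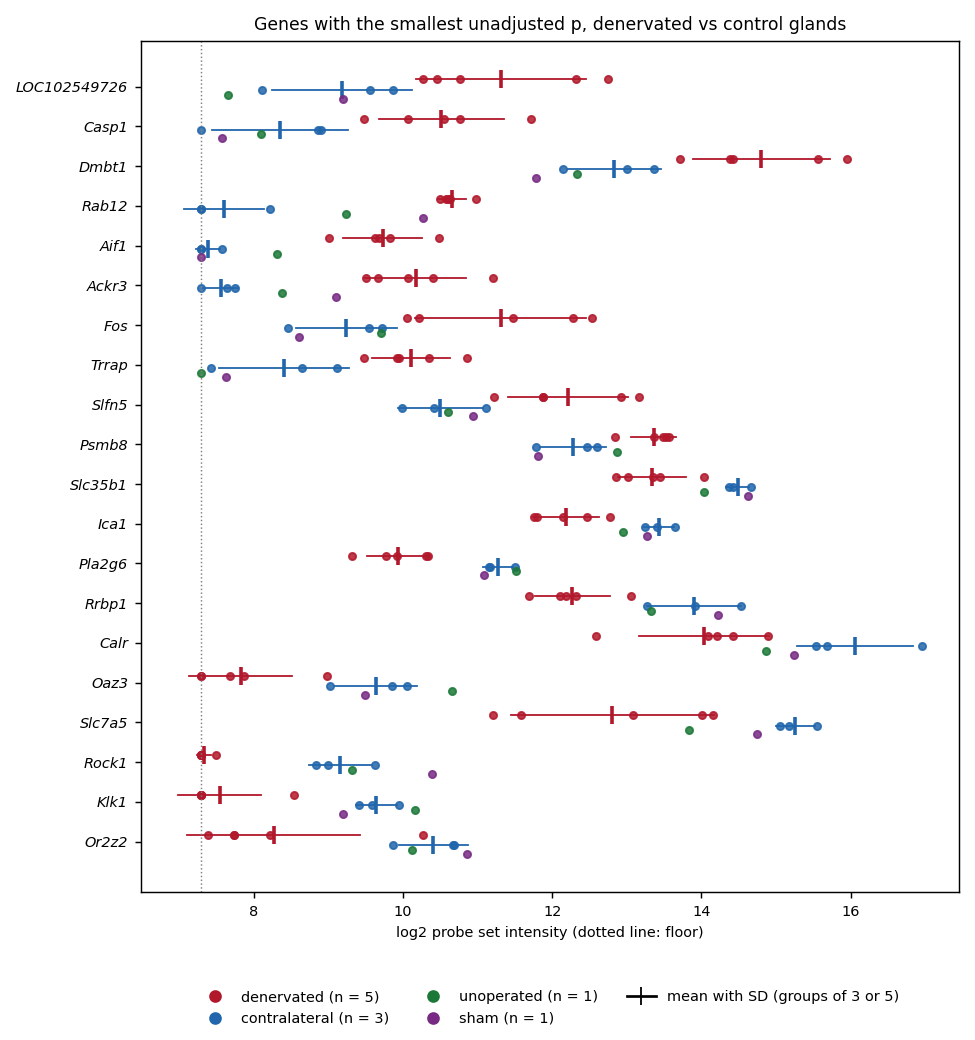
Log2 probe set intensity (horizontal axis) of the 20 genes named by the smallest unadjusted p in denervated against control glands; each point is 1 gland, coloured by group, bars are the mean with SD of denervated and contralateral glands, and the dotted line is the floor. Dmbt1 averaged 14.81 in denervated and 12.52 in control glands, and none of the 20 passed the test.

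Of 28 gene lists tested by camera with the preset correlation, 10 passed, 7 higher and 3 lower in denervated glands. With a correlation estimated from the data 0 passed, the lowest adjusted p being 0.252, with 3 at an unadjusted p under 0.05, and fry gave 0, with 7. Other splits of the same 10 arrays into groups of 5 gave as many lists too often for chance to be excluded.

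Chaperones and translocation proteins of the endoplasmic reticulum, which fold and modify secreted proteins, were lower: 25 of 27 measured genes were lower, with a median log2 difference of -0.57 (camera adjusted p = 2.50e-09, adjusted p = 0.252 with an estimated correlation). No member passed over all genes, 7 passed when adjusted over the list alone, and 16 were lower at an unadjusted p under 0.05. Dad1 differed by -1.05 ± 0.30, Calr by -1.37 ± 0.43 at a second probe set, and the disulfide isomerase P4hb by -1.14 ± 0.36. The chaperone Hspa5 had a mean log2 intensity of 14.14 ± 0.42 (SD, n = 5) in denervated and 15.13 ± 0.70 (SD, n = 5) in control glands. The list score of denervated 1, the mean log2 difference from control glands, was 0.01, and those of the other denervated glands were -0.94, -0.39, -0.57 and -1.19. Control glands had scores from -0.29 (unoperated) to 0.51 (contralateral 3), a range that holds denervated 1. Genes of exocytosis and vesicle traffic were also lower, 35 of 45, with a median of -0.29 (camera adjusted p = 0.00353, adjusted p = 0.252 with an estimated correlation). For this list 0 members passed over all genes and 0 adjusted over the list alone, while 7 were lower at an unadjusted p under 0.05 by limma, among them Tmed10 (-0.80 ± 0.23), Napa (-0.74 ± 0.25), Gosr2 (-0.81 ± 0.33) and Stx1a (-1.37 ± 0.58). The score of denervated 1 for this list, -0.09, was within the range of the control glands, -0.17 to 0.10. With 3 sets of arrays as a block, chosen after the data were seen, in which denervated 2 and 5 form a set of their own, the exocytosis median was -0.10 and the list no longer passed (adjusted p = 0.135).

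Genes of antigen presentation were higher. All 20 measured genes of MHC class I and the interferon response were higher, with a median log2 difference of 0.58 (camera adjusted p = 2.51e-07, adjusted p = 0.252 with an estimated correlation). Over all genes 0 passed by limma, 2 passed adjusted over the list alone, Psmb8 and the interferon regulator Irf7 (2.17 ± 0.64), and 6 had an unadjusted p under 0.05. The antiviral Mx2 differed by 2.17 ± 0.73 and RT1-S3 by 0.80 ± 0.32. Of 10 genes of MHC class II, 8 were higher, with a median of 0.66 (camera adjusted p = 0.000406, adjusted p = 0.252 with an estimated correlation). Over all genes 0 passed by limma, and 4 passed adjusted over the list alone, the same number as had an unadjusted p under 0.05: RT1-DMb (1.41 ± 0.42), RT1-Ba (0.90 ± 0.27), RT1-Db1 (1.10 ± 0.36) and RT1-Da (1.05 ± 0.36). Macrophage and monocyte markers were higher for 14 of 17 genes, with a median of 0.54 (camera adjusted p = 0.000384, adjusted p = 0.252 with an estimated correlation). Leaving out each gland, this median was 0.35 to 0.95. Over all genes 0 passed by limma, 0 adjusted over the list alone, and 5 had an unadjusted p under 0.05, including Apoe (1.78 ± 0.50), Cyba (2.08 ± 0.69), Aif1 at a second probe set (1.63 ± 0.55) and the complement gene C1qb (1.01 ± 0.39). Denervated 1 had list scores of -0.08 for MHC class I, 0.02 for MHC class II and -0.15 for macrophage markers, all within the range of the control glands. For MHC class II denervated 4, with 0.23, was within it as well.

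Genes of the stroma and of contractile cells were higher. Of 50 extracellular matrix and fibroblast genes, 39 were higher, with a median of 0.49 (camera adjusted p = 1.29e-05, adjusted p = 0.289 with an estimated correlation). Pdgfra, a receptor of fibroblasts, differed by 1.15 ± 0.32, the protease inhibitor Timp2 by 1.38 ± 0.39, Mgp by 1.81 ± 0.56 and decorin, Dcn, by 1.35 ± 0.49. In this list 0 passed over all genes by limma and 0 adjusted over the list alone, with 13 higher and 2 lower at an unadjusted p under 0.05. Myoepithelial cells surround the secretory acini and contract to expel fluid. Of 16 myoepithelial and smooth muscle genes, 13 were higher, with a median of 0.86 (camera adjusted p = 1.86e-05, adjusted p = 0.252 with an estimated correlation), among them Cnn1 (1.45 ± 0.59), Tpm4 (0.51 ± 0.21), Krt5 (1.34 ± 0.58) and Tpm2 (1.25 ± 0.54). The median of this list was 0.54 to 1.08 leaving out each gland. Here 0 passed over all genes by limma, 0 adjusted over the list alone and 6 were higher at an unadjusted p under 0.05. For matrix genes denervated 1, 3 and 4 had scores of 0.03, 0.40 and -0.03, within the range of the control glands, -0.47 to 0.43, and only denervated 2 and 5 lay above it. In these 2 glands blood cell genes (1.65 and 1.70) and cell cycle genes (1.08 and 0.97) also had their highest scores, and the 2 lay highest on the second principal component (31.1 and 70.1). With the 3 sets of arrays as a block the median was 0.17 for matrix and 0.22 for myoepithelial genes. For myoepithelial genes denervated 1 had -0.28, within the range of the control glands.

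Ribosomal protein genes were higher for 39 of 42, with a median of 0.34 (camera adjusted p = 2.51e-07, adjusted p = 0.343 with an estimated correlation). Leaving out each gland, this median was 0.20 to 0.44. Members included Rps6 (0.66 ± 0.23), Rpl22 (0.69 ± 0.24), Rpl3 (0.88 ± 0.35) and Rpl39 (0.58 ± 0.25), and 0 passed over all genes by limma, 0 adjusted over the list alone and 7 were higher at an unadjusted p under 0.05. Denervated 3 and 4 had ribosomal scores of -0.11 and 0.12, within the range of the control glands. Heat shock and oxidative stress genes were higher for 25 of 36, with a median of 0.20 (camera adjusted p = 0.0347, adjusted p = 0.252 with an estimated correlation). Their median was 0.10 to 0.22 leaving out each gland. This list no longer passed with quantile normalization (adjusted p = 0.111), or without the unoperated gland (0.119), denervated 3 (0.0824), denervated 4 (0.0535) or contralateral 1 (0.0506). Its scores were 0.11 to 0.20 in denervated glands and 0.18 in the sham gland. Its members Gpx2 (0.75 ± 0.28), Gpx3 (0.90 ± 0.36), Nfe2l2 (0.78 ± 0.32) and Gsta1 (0.62 ± 0.27) were among 4 with an unadjusted p under 0.05, and 0 passed over all genes by limma or adjusted over the list alone. Genes known from salivary glands, several of which lacrimal glands also express, were lower for 9 of 10, with a median of -1.10 (camera adjusted p = 0.00810, adjusted p = 0.252 with an estimated correlation). Over all genes 0 passed by limma, 1 passed adjusted over the list alone, Klk1, and 3 had an unadjusted p under 0.05. Smr3b differed by -2.19 ± 0.75, Cyss by -1.03 ± 0.40 and Egf by -1.17 ± 0.57. Denervated 1 had a salivary score of -0.34, within the range of the control glands, -0.39 to 0.52. With the 3 sets of arrays as a block the median was 0.14 for ribosomal, 0.33 for MHC class II and -0.47 for salivary genes.

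**Figure D2:**
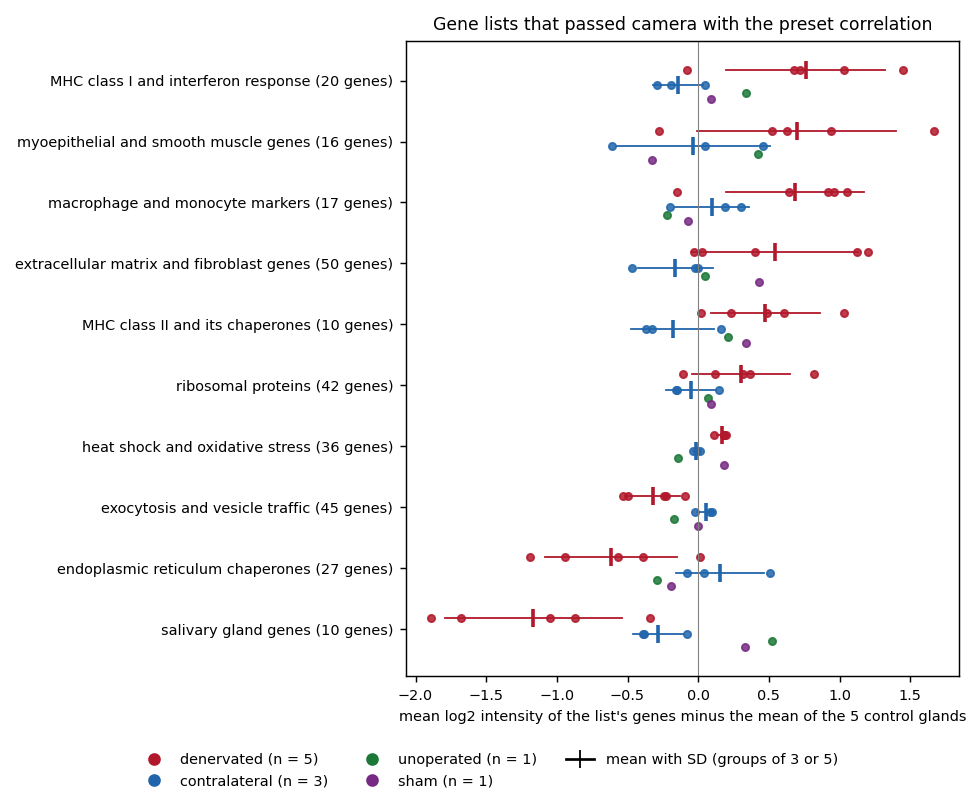
Mean log2 intensity of each passing list's genes minus the mean of the 5 control glands (horizontal axis), 1 point per gland coloured by group, with mean and SD bars for denervated and contralateral glands. For endoplasmic reticulum chaperones, denervated 1 lies at 0.01 and the other denervated glands between -1.19 and -0.39; with an estimated correlation, 0 of the lists passed.

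Among receptors and effectors of nerve-driven secretion, none passed the test. The muscarinic receptors, which receive the parasympathetic signal, had log2 differences of -0.99 ± 0.56 for Chrm2, -0.62 ± 0.53 for Chrm1, and 0.17 ± 0.65 and -0.15 ± 0.23 for 2 probe sets of Chrm3, which differ in sign. The receptor of vasoactive intestinal peptide, Vipr1, differed by -0.76 ± 0.62 and -0.40 ± 0.62, the adrenergic receptor Adra1a by 0.05 ± 0.67, the peptide Npy by -0.24 ± 0.73, and the water channel Aqp5 by 0.17 ± 0.35 and 0.23 ± 0.33. Rab3d, a GTPase of secretory granules, differed by -0.53 ± 0.26 and was below all controls in 5 of 5 denervated glands (limma adjusted p = 0.522). Vip fell under the filter on dim probe sets. Among 44 genes of autonomic receptors and calcium signalling the median was -0.18 (camera adjusted p = 0.692), with Prkaca at -1.10 ± 0.48.

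The other lists did not pass. Lacrimal secretory proteins had a median of -0.22 while the test's direction was up (camera adjusted p = 0.970), with 0 members past the threshold over all genes by limma and 2 adjusted over the list alone, Dmbt1 and Cst3 (1.26 ± 0.35). Ion and water transport genes, including Slc12a2 (0.87 ± 0.35) and Atp2a2 (-0.59 ± 0.24), had a median of -0.14 against a mean of 0.05 (adjusted p = 0.551), and T and natural killer cell markers, including Coro1a (2.33 ± 0.66) and Cd53 (1.20 ± 0.38), a median of -0.20 against a mean of 0.06 (adjusted p = 0.551). Medians and camera adjusted p were 0.66 and 0.133 for mast cell markers, 0.03 and 0.164 for inflammatory cytokines and acute phase proteins, and 0.37 and 0.164 for duct keratins. They were -0.24 and 0.943 for nerve and Schwann cell genes, -0.38 and 0.551 for endothelial genes, 0.23 and 0.290 for adipocyte genes, and 0.67 and 0.0908 for blood cell genes. Skeletal muscle genes had a median of -0.01 with the test's direction up (0.970), and oxidative phosphorylation genes a median of 0.02 against a mean of -0.01 (0.956). Lipid and sterol synthesis had -0.20 and 0.290, cell cycle 0.24 and 0.0652, apoptosis 0.06 and 0.185, immediate early genes 0.30 and 0.0908, and polyamine and amino acid metabolism -0.18 and 0.197. Of the B and plasma cell markers 3 were measured, too few to test.

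RNA quality was measured on control probe sets of 3 genes. The log2 ratio of the 3' to the 5' control probe set in denervated minus control glands was -0.16 for beta-actin (exact permutation test, two-sided, p = 0.389), 0.06 for GAPDH (exact p = 0.746) and 0.40 for hexokinase (exact p = 0.619), with n = 5 in each group. Leaving out each gland gave -0.23 to -0.04 for beta-actin, -0.08 to 0.17 for GAPDH, and for hexokinase 0.18 (without contralateral 2) to 0.99 (without denervated 1, exact p = 0.111). All 3 had a Benjamini-Hochberg adjusted value of 0.746, and the smallest p the exact test allows is 0.00794.

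The second comparison set denervated against contralateral glands. Rab12, a small GTPase, had a log2 intensity of 10.66 ± 0.18 (SD, n = 5) in denervated and 7.60 ± 0.54 (SD, n = 3) in contralateral glands, an 8.34-fold higher level, with 2 contralateral glands at the floor. Lgals3bp, a secreted binding partner of galectins, was 4.78-fold higher and the scavenger receptor Ackr3 6.11-fold higher. Calr, Rrbp1 and the amino acid transporter Slc7a5 had lower levels, by -2.03 ± 0.47, -1.64 ± 0.36 and -2.46 ± 0.60 (log2 difference ± SE). All 5 denervated glands lay beyond all 3 contralateral glands for each of these. The unoperated and sham glands also lay above all 3 contralateral glands for Rab12 (9.23 and 10.27) and Lgals3bp (11.09 and 11.84). Denervated glands averaged 11.52 for Lgals3bp, so low contralateral levels contribute to these 2 differences. For Ackr3 the unoperated and sham glands had 8.38 and 9.10, against 10.17 in denervated and 7.56 in contralateral glands.

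By limma 0 of 6118 probe sets passed, with 438 at an unadjusted p under 0.05, 254 higher and 184 lower. Rab12 had the smallest adjusted p, 0.155, and passed as the only probe set without a variance trend (adjusted p = 0.0413) and with array weights (0.0247), both alternatives to the main test. The other genes named here had an adjusted p of 0.634. Among them, higher in denervated glands, were Dmbt1 (1.97 ± 0.47), Aif1 (2.34 ± 0.56), Nbl1 (2.13 ± 0.52), Fat2 (1.98 ± 0.52), Plpp3 (2.30 ± 0.61, and 0.35 at another probe set) and Slfn5 (1.71 ± 0.45). Cnrip1 was at least 4.31-fold higher, all 3 contralateral glands being at the floor. Lower were Ica1 (-1.24 ± 0.29), Slc35b1 (-1.15 ± 0.29), Klk1 (-2.10 ± 0.57, and -0.11 at another probe set), the sodium chloride cotransporter Slc12a3 (-1.62 ± 0.44), Pla2g6 (-1.34 ± 0.37), the desaturase Scd2 (-1.32 ± 0.38) and Shank1 (-1.72 ± 0.50). The unoperated and sham glands had log2 intensities of 10.21 and 10.18 for Nbl1, 10.38 and 10.21 for Plpp3, and 9.51 and 11.05 for Cnrip1. Denervated glands averaged 10.52, 10.31 and 9.39, so for these genes the contralateral glands were the low ones. For Dmbt1, Aif1, Fat2 and Slfn5 the unoperated and sham glands both lay below all denervated glands. Among the lower genes, these glands had 10.34 and 9.21 for Shank1, against 9.39 in denervated and 11.11 in contralateral glands. They had 9.92 and 10.65 for Slc12a3, against 9.51 and 11.13, so high contralateral levels contribute to both differences. For Slc35b1 and Scd2 denervated 1 was at or above the unoperated gland. For Ica1, Klk1 and Pla2g6 the unoperated and sham glands lay above all denervated glands.

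Of 28 gene lists 8 passed camera with the preset correlation, 6 higher and 2 lower, and with an estimated correlation 0 passed, with 5 at an unadjusted p under 0.05 (fry 0, with 6). Endoplasmic reticulum chaperones had a median log2 difference of -0.77 (camera adjusted p = 2.63e-14, adjusted p = 0.250 with an estimated correlation), with 7 members past the threshold adjusted over the list alone and 0 over all genes. Exocytosis genes had a median of -0.35 (0.000132, and adjusted p = 0.250 with an estimated correlation). MHC class I had a median of 0.68 (1.59e-07) and MHC class II of 0.76 (0.000126), each with 2 members past the threshold adjusted over the list alone and each with adjusted p = 0.250 with an estimated correlation. Macrophage markers had a median of 0.50 (0.00793, and adjusted p = 0.250 with an estimated correlation), and no longer passed without contralateral 1 (0.0544) or denervated 3 (0.0504). Extracellular matrix genes had a median of 0.56 (3.04e-06) and myoepithelial genes of 0.78 (0.000108), each with adjusted p = 0.321 with an estimated correlation. Ribosomal proteins had a median of 0.40 (3.04e-06, and adjusted p = 0.361 with an estimated correlation). Exocytosis, macrophage, matrix, myoepithelial and ribosomal genes had 0 members past the threshold adjusted over the list alone or over all genes by limma. Salivary gland genes (0.0900) and heat shock genes (0.152) did not pass. Other splits of these 8 arrays also gave as many lists too often for chance to be excluded.

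The third comparison set denervated glands against the unoperated and sham glands, 2 glands treated differently and averaged. Arl11, an ADP-ribosylation factor-like protein, was 10.5-fold higher and the mitochondrial protease Oma1 6.73-fold higher in denervated glands, with the unoperated gland at the floor for both. Igf1, insulin-like growth factor 1, was 4.53-fold higher at one probe set, while others differed by 0.78 and -0.07. Smr3b, a secreted salivary protein, was lower by -3.51 ± 0.88 (log2 difference ± SE) and the receptor tyrosine kinase Ros1, at the floor in 3 denervated glands, by -3.15 ± 0.79. By limma 0 probe sets passed, with 483 at an unadjusted p under 0.05, 207 higher and 276 lower. Arl11, Oma1, Igf1, Dmbt1 (2.75 ± 0.54) and thioredoxin reductase Txnrd1 (2.80 ± 0.55, and 0.47 at another probe set) had an adjusted p of 0.275, and Smr3b, Ros1, Rock1 (-2.53 ± 0.62), Rrbp1 (-1.50 ± 0.42) and Cyss (-1.68 ± 0.47) of 0.616. Contralateral glands averaged 10.81 for Oma1, 10.68 for Igf1 and 9.88 for Txnrd1, against 10.62, 10.78 and 10.10 in denervated glands. For these genes the unoperated and sham glands were thus the low ones. For Arl11 and Dmbt1 contralateral glands averaged 10.14 and 12.84, against 11.13 and 14.81 in denervated glands. Without denervated 1, 5 probe sets passed (Errfi1, C3, Dmbt1, Cyba and 1 with no symbol), named after their values were seen. Leaving out the unoperated gland left the sham gland alone. Against it, Ndufb8, Ddx39b and Lcn2, also named after their values were seen, had log2 differences of 4.77, 3.92 and 8.13. These values rest on 1 gland, which was at the floor for Lcn2.

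The fourth comparison asked whether contralateral glands differed from the unoperated and sham glands. Oma1 was higher in the 3 contralateral glands by 2.94 ± 0.58 (log2 difference ± SE), Igf1 by 2.08 ± 0.49 (1.07 and 0.31 at other probe sets), the histone gene Hist4h4 by 2.96 ± 0.73 and Arl11 by 2.41 ± 0.70. Txnrd1 was higher by 2.58 ± 0.60 at one probe set and differed by -0.26 at another. Cnrip1, which binds a cannabinoid receptor, was at least 7.98-fold lower, all 3 contralateral glands being at the floor. Pkn2 was lower by -2.55 ± 0.67, Lgals3bp by -2.20 ± 0.59 (-0.95 at another probe set), Adap1 by -1.71 ± 0.46 (-0.12 at another) and Rab12 by -2.15 ± 0.60. By limma 0 probe sets passed, with 299 at an unadjusted p under 0.05, 93 higher and 206 lower, and the smallest adjusted p was 0.547. Against the sham gland alone, Ndufb8, named after its value was seen, had a log2 difference of 4.80. Denervated glands differed from the same gland by 4.77, so for Ndufb8 the sham gland was the low one.

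The sham gland and the unoperated gland were compared as values only. Sham intensity was over 4-fold above unoperated for 448 probe sets and over 4-fold below for 267, and the correlation of log2 intensity across probe sets, which are not independent replicates, was 0.807. For genes chosen after their values were seen, the unoperated gland had an Oprpn intensity of 547722 and the sham gland 119, while Dnase1, a secreted nuclease, had 11714 and 721537 at one of its probe sets. On the first principal component the sham gland lay at -54.3, near contralateral 1 (-50.0) and denervated 1 (-51.7). The unoperated gland lay at -5.30. Sham is thus among the arrays that stand apart, and these differences cannot be assigned to the sham operation.

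**Figure D3:**
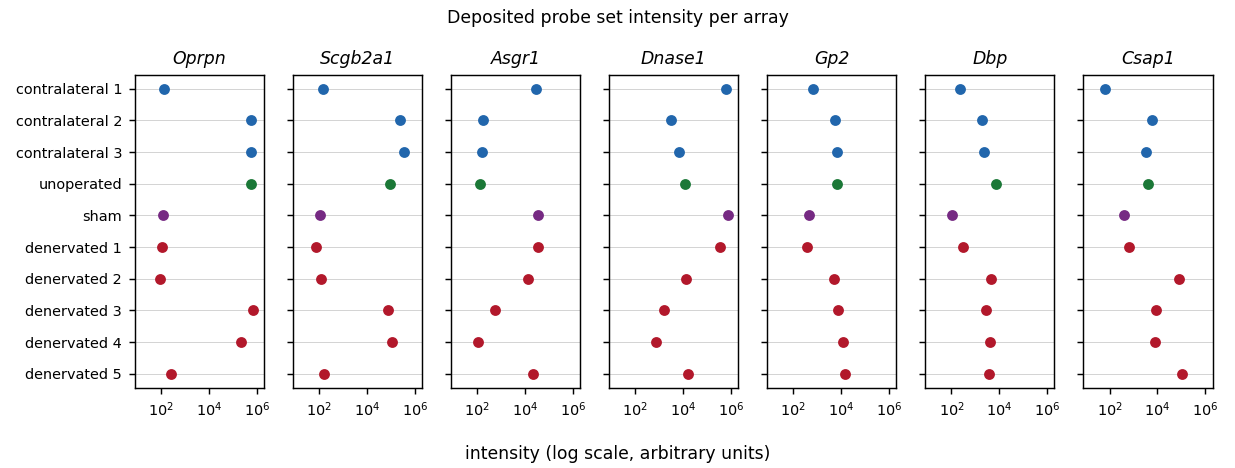
Deposited intensity on a log axis for 7 transcripts, 1 point per gland on labelled lines and coloured by group. Oprpn runs from 89 in denervated 2 to 705748 in denervated 3, and contralateral 1, sham and denervated 1 hold the highest Dnase1 intensities.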

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

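No test in this part was chosen after its result was seen. The same 5 denervated glands were examined for 63 quantities. For each, the highest or lowest gland was set against the others by its gap to the nearest, and in 9 it stood far from the rest. Chance flags about 1 in 20 independent quantities, but these share glands and genes, so that rate is only a rough guide. Among log2 intensities, Psmb8 in denervated 1 was 12.84 (the other denervated glands 13.36 to 13.57), Rab12 in denervated 2 was 10.98 (10.50 to 10.63) and Or2z2 in denervated 1 was 10.27 (7.38 to 8.22). Chrm1 in denervated 2 was 7.74 (9.55 to 10.14). Klk1 in denervated 1 was 8.54 and Rock1 in denervated 3 was 7.49, where the other denervated glands were at the floor of 7.29, which fixes the outcome for these 2, so the 9 overstate the count against chance. The adipocyte list score of denervated 1 was -0.04 (0.44 to 0.54), and the heat shock list score of denervated 4 was 0.11 (0.18 to 0.20). The log2 ratio of the 3' to the 5' hexokinase probe set in denervated 1 was -1.33 (1.47 to 1.81). Of the 9, denervated 1 gave 5 and denervated 2 gave 2.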

How the results depend on the processing

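Fits with sets of arrays as a block, the fit of 7 arrays, and leaving out glands for the RNA ratios were chosen after the data were seen. The sets were drawn from the first principal component and from Scgb2a1 and Dnase1 levels. No list that passed changed direction under any alternative run, while lists that did not pass did, such as skeletal muscle genes with medians of -0.25 to 0.31 leaving out each gland. For the named genes, 3330 settings kept direction and side of the threshold, 30 brought a gene past it and 23 turned the direction; for passing lists 336 kept the call and 64 lost it, among them exocytosis with 3 sets of arrays as a block (median -0.10, adjusted p = 0.135). The median log2 difference of all genes in denervated against control glands was -0.08 as deposited and 0.04 with median scaling; against the unoperated and sham glands it was -0.17 and 0.14.

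Probe sets passing without the filter were 13 for denervated and 7 for contralateral against the unoperated and sham glands, all lower; the first group was entirely at the floor for 1 and 4 of them, and the cause was not tested. For denervated against contralateral glands, no variance trend gave 1 and array weights gave 1, Rab12 in both; the cause was not tested. Leaving out each gland gave 0 to 70 probe sets for denervated against control (70 without denervated 1), 0 to 0 against contralateral, 0 to 5 against the unoperated and sham glands (5 without denervated 1, 3 without the unoperated gland), and 0 to 1 for contralateral against these; a lone gland was assumed to vary like the other groups. Without denervated 1 and with the array set block, 0 passed. In the 7 arrays 13 passed for denervated against the unoperated gland, all higher, and with 3 sets of arrays as a block 1 passed, Smr3a; the cause was not tested. Lists passing were 0 and 0 with an estimated correlation, 0 and 0 with fry, and 0 with either block and an estimated correlation, the cause not being tested; leaving out each gland gave 9 to 12 and 8 to 11.

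Values that turned direction were not past any threshold, and the cause was not tested. Adra1a was -0.05 with the floor at the 10th percentile, -0.01 with array weights and -0.34 to 0.59 leaving out each gland. Aqp5 was -0.02 with the array set block, -0.23 at both probe sets in the 7 arrays and without denervated 1 with the block, and -0.08 to 0.41 leaving out each gland. Chrm3 was -0.26 without the unoperated gland, -0.26 to 0.61 leaving out each gland, and 0.04 at its other probe set with the 3 sets. With the 3 sets Vipr1 was 0.11 and Hbb -0.36. Leaving out each gland, Npy was -0.59 to 0.07 and the GAPDH ratio -0.08 to 0.17.

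Whether the glands' numbers pair the samples could not be settled. Same-numbered contralateral and denervated glands deviated together with correlations of 0.49, 0.04 and 0.16, and contralateral 2 and 3 did not correlate best with their own number. Contralateral 1 and denervated 1 were each other's closest array (correlation 0.898), but both belong to the arrays that stand apart. With the replicate block 0 and 0 probe sets passed by limma (675 and 332 at an unadjusted p under 0.05), and 10 and 9 lists. Low signal limits the dim probe sets, since the floor lay at an intensity of 156.2.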

Other observations

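Tests chosen after the result was seen are those of salivary tissue, RNA degradation, time of day, scaling, the share of acinar cells, the arrays that stand apart, and the splits for the endoplasmic reticulum median and for lists against contralateral glands.

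Several abundant secretory transcripts were present in 5 glands and near background in the other 5, whatever their group. Oprpn, a proline-rich secreted protein, had intensities of 564740 and 556715 in contralateral 2 and 3, 547722 in the unoperated gland, and 705748 and 213171 in denervated 3 and 4. It had 138 in contralateral 1, 119 in sham, and 105, 89 and 253 in denervated 1, 2 and 5. Scgb2a1, a secretoglobin, followed the same glands, with 72 to 154 in these 5 and 74352 to 360033 in the others. Asgr1, a receptor for desialylated glycoproteins, went the other way, from 12716 to 35128 in the 5 glands that lacked Oprpn and 108 to 529 in the others. Csap1, a salivary protein, was highest in denervated 2 and 5, with 81350 and 103875. Pip and Spt1, also secretory, were abundant in all 10 glands.

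Contralateral 1, sham and denervated 1, glands of 3 groups for which time of day was the only biological explanation weighed, also shared Dnase1 intensities, at one probe set, of 621186, 721537 and 329146, where the other glands had at most 15271, and low Gp2, with 631, 429 and 385 against at least 5208. Csap1, picked after its values were seen, was low in these 3 glands, at 66, 397 and 670 against at least 3277 in the others. A single gene does not decide whether they held salivary tissue. Of 9 other salivary genes, 5 of them also lacrimal, 8 were higher (median log2 difference 0.72, with Oprpn at -11.78), and no salivary gland was measured. The 3 glands are mostly controls and the other 7 mostly denervated, and the salivary list was lower in denervated glands (median -1.10). Part of this difference may thus be the one between denervated and control glands. Salivary tissue is not excluded. A first bound on the median of 0.72, under 1, would have argued against it and was replaced after the value was seen. RNA degradation raises the 3' to 5' ratio, and GAPDH argues against it, with 0 of the 3 glands inside the range of the other 7 and all 3 below, while beta-actin, with 3 inside, showed no rise. The mean over the 3 genes differed by -0.41, also opposite to degradation, and 12 of the 120 sets of 3 glands lay as far from 0. The rule for this test used beta-actin and GAPDH only. It left degradation undecided because it counted GAPDH ratios outside the range on either side. Hexokinase, not part of that rule, went both ways, with log2 ratios of 2.38 in contralateral 1, -0.07 in sham and -1.33 in denervated 1. A difference in time of day at collection may contribute. The 3 clock genes tested, Dbp, Nr1d1 and Bmal1, each had a probe set outside the range of the other 7. Only 4 of 6 probe sets did, and the second Nr1d1 probe set had 2659 to 3509 in the 3 glands, within 846 to 9966. Per2, a clock gene not in the test, had 996, 199 and 1269, within 136 to 2312 in the other glands. This explanation was proposed from these values, and it does not address Dnase1.

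For the transcripts present in 5 glands, the sex of the animals could be a cause, as several are androgen-dependent in rat glands. Y-linked probe sets were near background, at most 3 glands lying 2-fold above the floor, so the sexes of the animals cannot be told apart here.

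Lower endoplasmic reticulum chaperones in denervated glands were weighed as the third pattern. Array scaling alone is argued against, since the list's median was -0.45 or lower with other scalings, and so are the arrays that stand apart, with -0.42 or lower without them or with 3 sets of arrays as a block. A lower share of acinar cells stays open: it raises the markers of every other type alike, and macrophage, matrix and myoepithelial genes shifted by 0.60 while endothelial and nerve genes shifted by -0.17, a difference of 0.77 (exact permutation p = 0.0635, n = 5 per group). This comparison cannot decide, since most of the second set came from the 39 measured nerve and Schwann cell genes, with 8 endothelial genes. Section of the nerve may change nerve genes directly. The effect of denervation itself, the biological explanation the design names, remains a hypothesis, since chance could not be excluded. Of 100 splits of the arrays, the real one included, 7 gave a list median as far from 0 (the real value -0.57, the highest other 0.71, whose sign only reflects which group is taken first).

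The counts of passing probe sets say nothing about chance, since with a real count of 0 every split gives as many, 100 of 100 for denervated against control glands (highest other 100) and 56 of 56 against contralateral glands (highest other 11). Chance was not excluded for the other counts, in which the real split is included. For denervated against control glands 13 of 100 splits gave as many probe sets at an unadjusted p under 0.05 (real 592, highest other 1233), and 15 as many lists (10 and 12). For denervated against contralateral glands, 18 of 56 gave as many probe sets at an unadjusted p under 0.05 (438 and 1017), and 17 as many lists (8 and 13). Of the 100 splits of all 10 arrays, the 3 with over 10 passing probe sets kept contralateral 1, sham and denervated 1 on one side; of the 56 splits of 8 arrays, the one with 11 set denervated 2, 3 and 5 apart.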
